A study of Drosophila melanogaster with 2 samples.

How the data were processed

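The samples were whole Drosophila melanogaster embryos collected over 0 to 24 h of development, from a transgenic strain that carries a fusion of CG14667 with eGFP, a green fluorescent protein used here as an epitope tag. Chromatin was fragmented by sonication to a range of 200 to 800 bp and immunoprecipitated with an antibody against GFP, per the labels' descriptions. The labels describe 2 biological replicates of 1 group, so no comparison between conditions was possible. Separate biological samples are recorded for both replicates.

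The files hold peak lists only. The authors' listings name a control file, filtered alignments and the dm6 assembly as the inputs, and the aligner, the peak caller and their versions are not given in the sources used here. Reads and read counts were not used here, so the sequencing depth of either replicate is unknown and no interval on a signal value could be derived from it. For each replicate, and for both replicates together, the authors deposited a ranked list of candidate peaks and a shorter thresholded list. IDR, the irreproducible discovery rate, starts from the ranks of a peak in the lists that are compared. It estimates how likely the peak is to belong to the part of the list that is not reproducible. The global IDR is the expected share of such peaks among all peaks ranked at least as high. Each replicate's own list also carries an IDR, and the rankings compared for it were not examined here. A conservative thresholded list and another, longer one were deposited for the series.

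Each peak carries a signal, which per the listings the authors' peak caller computed against a control and deposited in the lists. The listings do not give the signal's scale, so signals were used only to describe and rank peaks within a list, and for each replicate's value at the same peak. The authors also deposited an IDR score per peak, held at 1000 at its upper end. The deposited lists give −log10 of a q value and, in the ranked lists, −log10 of the global IDR, and the summit's offset from the start of the peak. No label assigns the per-replicate columns of the series' ranked lists to a replicate, so these columns were left out and replicate signals were taken from each replicate's own list.

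Every peak of the thresholded lists had a global IDR of 0.01 or less (a score of 830 or more). Some ranked peaks that met this limit were missing from the thresholded lists, and the listings name a further input file for those lists that was not used here. The main list was the conservative one. Location, gene and sequence analyses used its peaks on 2L, 2R, 3L, 3R, 4, X and Y, and peaks on scaffolds were left out of them. Coordinates are 1-based on dm6. Every peak end lay within the length of the same arm in the reference sequence, and transcription starts (24111) and genes were taken from Ensembl release 115.

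The tests were chosen before the data were examined. Overlap between the replicates' own lists needed 1 bp and was compared with 1000 circular shifts of 1 list within each arm (permutation test, one-sided). The share of summits within 500 bp of a start was compared with the same kind of shift, and with ranked summits that failed the threshold (Fisher's exact test, two-sided). Peak numbers per arm were compared with the arm's share of the length by exact binomial tests. A gene counted as bound when a summit lay within 500 bp of any of its starts, and 35 gene lists were tested by Fisher's exact test (one-sided, for more bound members) against 13945 protein-coding genes, or against 18164 genes for lists of non-coding genes. The lists were written from gene symbols, some genes belong to more than 1 of them, and the pattern for eggshell and yolk genes also took up Cp190, which encodes an insulator protein. Each of 20 motifs was searched within 50 bp of the summit and in a window of the same width centred 300 bp to the left (exact McNemar test, two-sided). Words of 8 bases were ranked on 2L, 2R and X, and the first 10 were tested again on 3L, 3R and 4. Starts within 1000 bp of each other were joined into promoter units for the comparison of head-to-head units with units on 1 strand. Soft-masked sequence, which marks repeats and low-complexity DNA, was counted within 50 bp of the summit. P-values were adjusted by the method of Benjamini and Hochberg within each family, with a threshold of 0.05, and shares carry 95% Wilson intervals that cover counting error only. Peaks and genes are not independent replicates, and p-values across them describe these 2 libraries.

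Genes were named by a rule fixed in advance. It took the gene with the nearest start to each of the 20 conservative peaks with the largest signal, CG14667, up to 4 bound members of each list with the largest signals, and the 8 Hox genes. Genes at counts of 5 or fewer that the rule did not cover were named after their values were seen. Alternatives covered the other thresholded list, each replicate's own list, other distances, windows, controls and backgrounds. A stricter global IDR of 0.001, the exclusion of peaks with a pooled signal under 40, and controls for base composition were added after the data were examined.

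Calculations were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The procedures were tested on simulated data with 3000 peaks. A planted promoter share of 42.2% was recovered as 42.2%, a planted 60.6% of shared peaks as 61.0%, and a planted odds ratio of 3.86 for head-to-head units as 3.80. A gene list with a planted bound share of 40% came out at 46.5% in that draw, and 0 of the 30 other coding lists passed. A motif planted at 10% of summits was found at 10.1% of them, and 0 of the 19 other motifs passed. The simulated summits lay at random positions, so they did not differ from their control windows in base composition, as the real summits did. Motif calls that come from base composition were therefore not covered by this simulation.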

Results

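CG14667 is a Drosophila gene on chromosome 3R, at 5375022 to 5376460 on the plus strand in dm6. Its 4 coding exons encode 337 amino acids, with 5 matches to the C2H2 zinc-finger pattern between residues 179 and 297. The series mapped where a GFP-tagged copy of this protein sat in the genome of whole embryos, by chromatin immunoprecipitation and sequencing in 2 biological replicates. Whole embryos of 0 to 24 h mix all embryonic tissues and stages, so a peak cannot be assigned to a cell type.

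The conservative list held 3083 peaks, of which 3029 lay on the chromosome arms and 54 on unlocalised scaffolds of X. The other thresholded list of the series held 3552 peaks. Replicate 1 had 2699 peaks in its own list and replicate 2 had 2146. The conservative peaks had a median width of 336 bp, covered 918 kb, and had a median pooled signal of 115 with a maximum of 2115. Among them were 89 peaks with a pooled signal under 40. The ranked list behind the conservative list held 129916 candidate peaks.

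The strongest peaks lay mostly at gene starts and were found in both replicates. The largest pooled signal, 2115, was upstream of Ugalt (FBgn0024994), which encodes a UDP-galactose transporter of the Golgi. This peak, on X at 2703711 to 2704056, had a signal of 1038 in replicate 1 and 1084 in replicate 2, and its summit was intergenic and 33 bp upstream of the start. CG14100 (FBgn0036889) came second with 1994, on 3L at 19590457 to 19590779, 97 bp upstream of the start. All 20 of the strongest peaks were in both replicates' own lists, 16 had a summit within 500 bp of a start, and at 11 of them starts of at least 2 genes lay within that distance.

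Several of these peaks lay near the starts of a pair of neighbouring genes. The peak next to Tcs5 (FBgn0035590), on 3L at 5139340 to 5139651 with a pooled signal of 1740, also lay within 500 bp of a start of CHMP2B. The peak upstream of Art3 (FBgn0038306), on 3R at 15229376 to 15229687 with a signal of 1327, was shared with mRpS10, and that near CenG1A (FBgn0028509), on 2L at 13835306 to 13835604 with a signal of 1310, with mRpS23. Genes for subunits of the mitochondrial ribosome were nearest to 2 of the 20 peaks. These were mRpL41 (FBgn0034001), on 2R at 15217600 to 15217908 with 1665, and mRpL23 (FBgn0035335), on 3L at 2373457 to 2373752 with 1194 and a summit in the 5' UTR.

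The peak at ph-p (FBgn0004861), a Polycomb group gene, lay on X at 2137206 to 2137522 with a pooled signal of 1512 and a summit in an intron, 495 bp upstream of the nearest start. The peak at Chro (FBgn0044324), which encodes the chromatin protein Chromator, lay on 3L at 22878740 to 22879058 with 1322 and a summit in the 5' UTR. The peak at Adf1 (FBgn0284249), a transcription factor gene, lay on 2R at 6662906 to 6663216 with 1386, in an intron 779 bp downstream of the nearest start. In total 4 of the 20 summits lay over 500 bp from a start. Besides Adf1 they were nearest to CG11050 (1636, in an intron), CG32772 (1205, in an intron) and lncRNA:CR45643 (1163, intergenic).

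The remaining strong peaks were nearest to CG7601 (pooled signal 1422), CG5611 (1281), asRNA:CR45928 (1263), Atat (1188), CG8320 (1166), GstE13 (1143) and PNPase (1139). The peak at asRNA:CR45928, on 2R at 23850257 to 23850544, lay in an exon of that antisense RNA and within 500 bp of a start of eIF6, a translation factor gene.

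The 2 replicates marked largely the same places. Of the 2678 peaks on the arms in replicate 1's own list, 1709 overlapped a peak of replicate 2, which is 63.8%. In the reverse direction 1693 of 2052 peaks overlapped, or 82.5%. Shifted lists shared 0.831% on average and at most 1.57% (permutation test with 1000 circular shifts, one-sided, p = 0.001, the smallest they can give). Peaks of replicate 1 with no partner had a median signal of 54.98, against 93.2 for those with one, and 72.8% of the unpartnered ones overlapped a candidate in replicate 2's ranked list. Many such overlaps arise by chance, since shifted copies of these peaks overlapped a candidate in 40.6% of cases (SD 1.71, maximum 44.1%; permutation test with 100 shifts, one-sided, added after the data were examined, p = 0.0099, the smallest they can give).

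Signals at shared peaks followed each other. Across the 1709 pairs Spearman's rho was 0.81 (permutation test with 100000 resamples, p = 1e-05, the smallest they can give). Pearson's r was 0.95 on the signals and 0.77 on their log2 values. These are correlations across peaks, which are not independent replicates. The median log2 ratio of replicate 1 to replicate 2 was 0.22, with an SD of 0.65 across pairs. The SD was 0.40 for pairs with summits within 100 bp of each other and 0.43 for pairs with 50% reciprocal overlap.

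**Figure D1:**
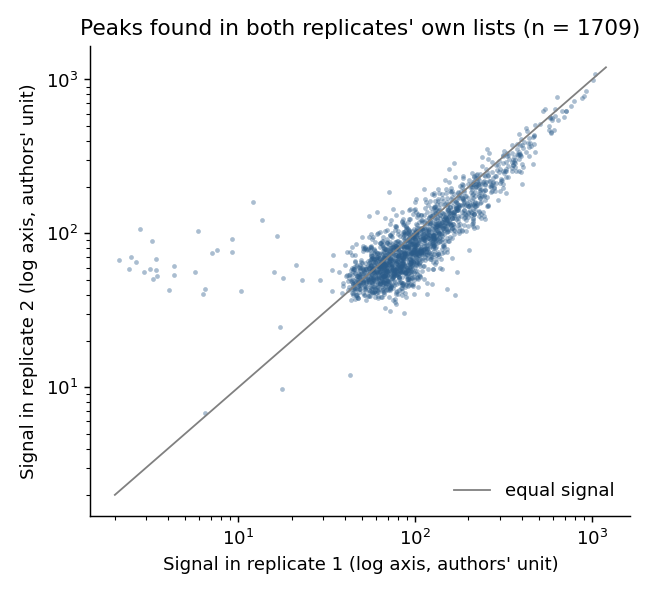
Signal of each peak found in both replicates' own lists, replicate 1 on the x axis and replicate 2 on the y axis, both on log axes in the authors' unit; each point is 1 of 1709 pairs and the line marks equal signal. Most points follow the line (rho = 0.81), apart from a few pairs with a low signal in replicate 1. Some of those hold a replicate 2 peak that also overlapped a stronger replicate 1 peak, since any overlap made a pair.

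Peaks gathered just upstream of gene starts. Of the 3029 conservative summits on the arms, 1383 lay within 500 bp of an annotated start, which is 45.7% (95% Wilson interval 43.9 to 47.4%). Among the 1304 summits within 500 bp of a protein-coding start, 1122 were upstream of it (86.0%), with a median position of -117 bp. An exact binomial test against an even split, not among the tests fixed in advance, gave p = 1.72e-165. A further 35.8% of summits lay in introns and 15.5% between genes. Summits in a coding exon and over 500 bp from a start made up 0.957%, against 13.4% of shifted positions.

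Shifted summits lay near a start in 13.4% of cases (SD 0.693 across shifts, maximum 15.5%; permutation test, one-sided, p = 0.001, the smallest 1000 shifts can give). Ranked summits that failed the threshold did so in 12.1% (14984 of 123365), an odds ratio of 6.08 in Fisher's exact test, whose p was too small to be represented. Neither comparison tests for nonspecific signal at the starts of transcribed genes. The share rose with signal. It was 67.0% among the 300 strongest peaks (95% Wilson interval 61.5 to 72.1%) and 37.1% among the 1029 weakest (34.2 to 40.1%).

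**Figure D2:**
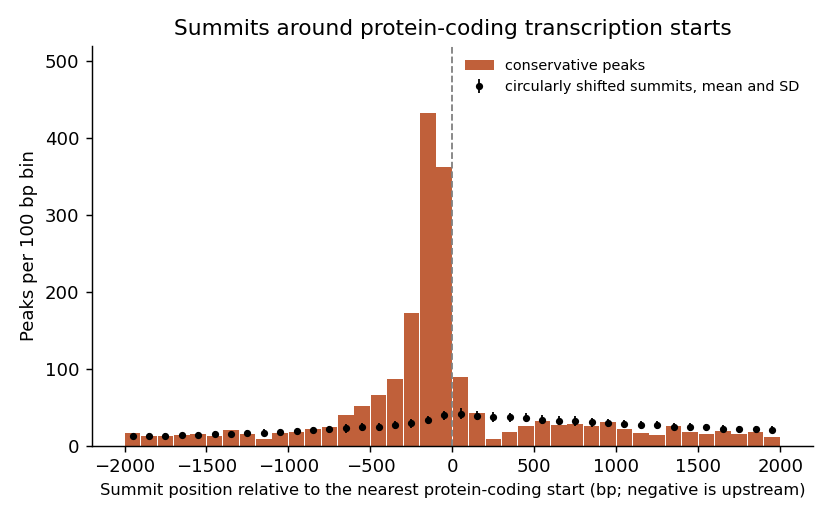
Number of conservative summits (bars) per 100 bp bin by position relative to the nearest protein-coding start, in bp with negative values upstream; black points and lines give the mean and SD of 100 sets of circularly shifted summits. The bin from -200 bp held 433 summits against 33.7 in the shifted sets, and the bin from 200 bp held 8 against 37.1.

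Promoter units with head-to-head starts, from which genes run apart, had a summit near their midpoint more often than units on 1 strand. Whether the summit lay between the starts was not checked. A head-to-head unit holds more than 1 start, a unit on 1 strand may hold only 1, and the units were not matched on this number. Of 3018 promoter units with head-to-head starts, 588 had a summit within 500 bp of their midpoint (19.5%). Of 11937 units with starts on 1 strand, 618 did (5.18%). The odds ratio was 4.43 (Fisher's exact test, two-sided, p = 1.52e-120). With units limited to those holding a protein-coding start, a restriction chosen after the data were examined, it was 4.20.

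Cytoplasmic ribosomal protein genes had a summit at a start more often than other genes. A summit lay at the start of 33 of the 86 (38.4%), against 1755 of 13945 protein-coding genes (12.6%). The odds ratio was 4.39 (Fisher's exact test, one-sided, adjusted p = 3.97e-08). RpL34b had the largest signal of them (441.7), followed by RpS27 (351.2), RpL32 (279.8) and RpL7 (263.9). Computed after the data were examined, the GC content of the 35 summits at these starts was 4.14 percentage points above that of their flanks (SE 1.89), where at 1348 other starts it was 12.1 points below (SE 0.357). Nonspecific signal at highly transcribed genes was not excluded for these peaks. It was not tested for peaks at the starts of other genes.

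Genes of vesicle transport, which moves proteins between the compartments of the secretory and endosomal systems, were the other list past the threshold. Of 94 such genes 22 were bound (23.4%, odds ratio 2.14, Fisher's exact test, adjusted p = 0.0463). The largest signals were at Arl1 (824.6), AP-1sigma (506.2), alphaCOP (425.5), a subunit of the COPI coat, and Sec6 (252.2), a subunit of the exocyst. Arl1 and the chromatin remodeller gene brm shared 1 peak. This call was lost under 4 of 11 settings, among them the other thresholded list (adjusted exact p = 0.061) and the assignment of each peak only to the gene with the nearest start (adjusted exact p = 0.676). The 11 settings include the main one and a limit of 0.01 on the global IDR, which removed no peak and gave the same result.

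Another 5 lists had an unadjusted p below 0.05 and did not pass after adjustment. Of 33 DNA repair genes 10 were bound (30.3%, adjusted exact p = 0.0509), with the largest signals at mei-41 (414.8), the fly ATR kinase gene, Irbp (324.0), Ercc1 (237.9) and mus312 (228.5). Of 93 genes for RNA polymerase, general factors and Mediator 21 were bound (22.6%, adjusted exact p = 0.0509), among them Taf5 (417.7), MED27 (346.7), Polr2H (319.2) and TfIIA-L (305.4). Each of these lists passed under 4 of 11 settings. With each peak assigned only to the gene with the nearest start, the second list had 8 of 93 bound (8.60%), slightly below the background of 8.71% (odds ratio 0.987). Insulator and chromosome architecture genes had 8 of 28 bound (28.6%, adjusted exact p = 0.132), with Chro, Cp190 (349.2), the cohesin subunit gene SA1 (304.1) and Trl (186.8), which encodes GAGA factor, and passed under 1 of 11 settings, in replicate 2's own list (adjusted exact p = 0.0274). Mitochondrial ribosomal protein genes had 15 of 73 bound (20.5%, adjusted exact p = 0.182), but 7 of 73 (9.59%, against 8.71% of the background) with the nearest gene only. Genes of the ZAD zinc-finger family, drawn up from memory and incomplete, had 6 of 20 bound (30.0%, adjusted exact p = 0.182), with Sry-delta at 357.3 and M1BP at 181.7.

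Some other lists held single strong places without passing the test in the conservative list. Polycomb and trithorax group genes had 7 of 28 bound (adjusted exact p = 0.236), including ph-p, brm and E(z) (416.4). Splicing factors had 8 of 35 (adjusted exact p = 0.253), proteasome subunits 7 of 32 (0.346 after adjustment) and translation factors 9 of 52 (0.640 after adjustment), with eIF6 at a signal of 1263 and eEF5 at 373.9. Splicing factors passed under 1 of 11 settings, in replicate 1's own list, with 11 of 35 (31.4%, adjusted exact p = 0.011). Heat shock and chaperone genes had 5 of 27 bound, led by Hsp27 (654.6). Neurogenesis genes had 6 of 34, led by elav (503.4), a pan-neuronal RNA-binding protein gene, and numb (346.0). This share fell below the background in replicate 2's own list, with 3 of 34 (8.82% against 9.64%, odds ratio 0.907), and within 250 bp, with 1 of 34 (odds ratio 0.280). In the respiratory chain list 10 of 88 were bound, in the list of tRNA synthetases 5 of 32, and in that of replication and cell cycle genes 4 of 38. The first and last of these lay below the background in the conservative list and above it in replicate 2's own list.

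Lists of patterning genes passed no test of more or fewer bound members. None of the 8 Hox genes (Dfd, Scr, Antp, abd-A, Ubx, Abd-B, lab and pb), which set segment identity, had a summit at a start. The nearest conservative summits were 12634 to 81046 bp away. None of the 8 pair-rule genes was bound either, and for both lists a count of 0 of 8 leaves a 95% Wilson upper limit of 32.4%. Of 14 maternal and gap genes 1 was bound, the anterior determinant bcd (169.4). The segment polarity list had 2 of 16, sgg (284.6) and nkd (208.5), and the dorsoventral list 2 of 23, tin (352.9) and cact (190.9). Neither tin nor cact had a peak at a start in replicate 2's own list, and the dorsoventral count was 0 of 23 there and 3 of 23 in replicate 1's own list. Within 1000 bp it was 5 of 23, above the background (odds ratio 1.59). The adjusted p for more bound members was 1 for each of these lists, and two-sided Fisher's exact tests, added after the data were examined, gave adjusted p from 0.817 to 1.

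**Figure D3:**
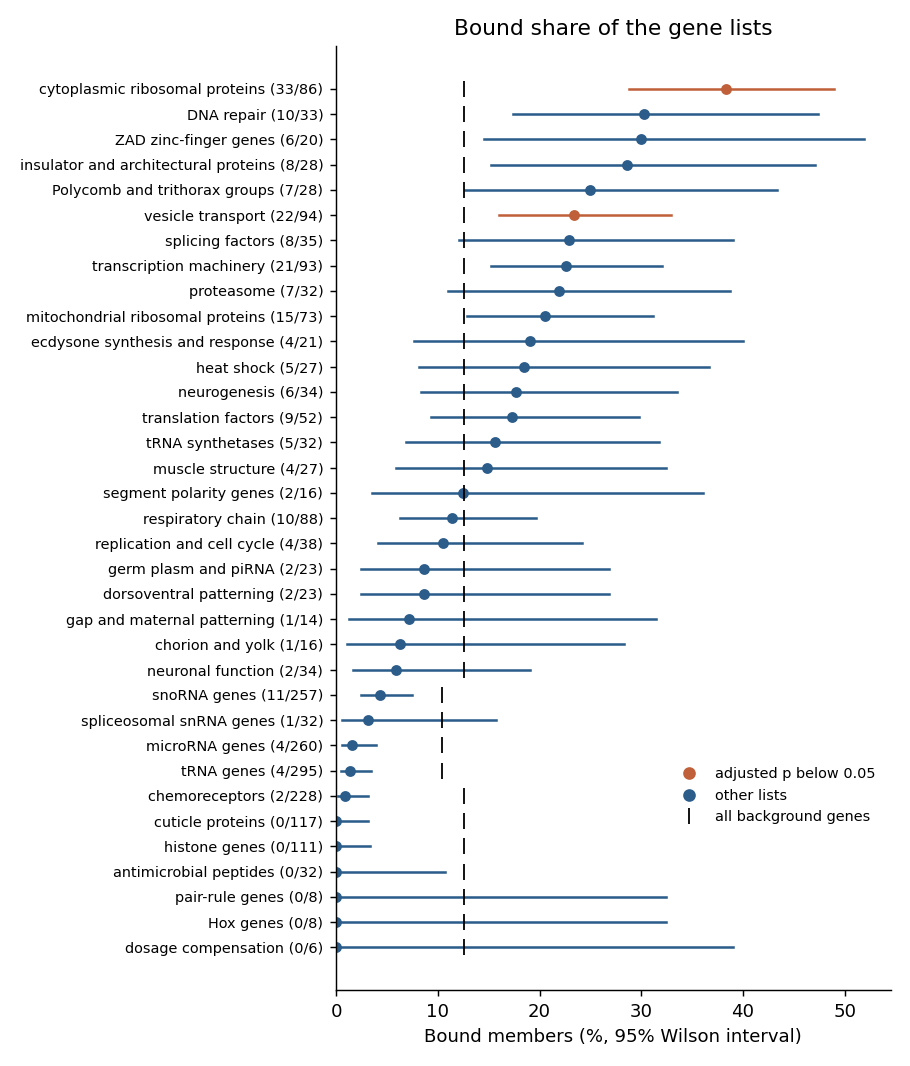
Bound share of each of the 35 gene lists in percent, with the bound and total members in brackets; points give the share, lines the 95% Wilson interval and black ticks the share of all background genes. Cytoplasmic ribosomal proteins (38.4%) and vesicle transport (23.4%) had an adjusted p below 0.05.

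In the conservative list the arms of chromosomes 2 and 3 carried peaks in proportion to their length, while chromosome X carried more, and 4 and Y few. With expectations taken from transcription starts in place of length, 2L also passed, with a ratio of 0.905 (exact binomial test, adjusted p = 0.0184). X held 618 peaks where 518 were expected from its length, a ratio of 1.19 (exact binomial test, adjusted p = 6.57e-06). Chromosome 4 held 1 where 29.7 were expected (adjusted exact p = 2.7e-11), upstream of PlexA at 1027169 to 1027393. A further 2 ranked peaks on 4 met the authors' limit and were missing from the conservative list. Only 33 candidates lay on 4, and 1 of 33 in the conservative list is not below the 3029 of 126482 on all arms, so the shortage was one of candidates. Y held 3 where 80.8 were expected (adjusted exact p = 3.62e-30), of which the strongest, intergenic at 787583 to 787918, had a pooled signal of 102.8, with the others at 788580 to 788915 and 3017817 to 3018152. By its share of transcription starts 21.8 peaks were expected on Y (adjusted exact p = 3.31e-06), and Y held 0 peaks in replicate 1's own list and 5 in that of replicate 2. Candidates on Y numbered 920, or 251 per Mb, against 858 to 1032 per Mb on 2L, 2R, 3L, 3R and X. Only 1.59 Mb of its 3667352 bp were unmasked, which the expectation from length does not take into account. For 2L, 2R, 3L and 3R the ratios were 1.02, 1.00, 1.04 and 0.961, with adjusted p of 0.734, 1, 0.391 and 0.391. Replicate 1's own list alone put 6 arms past the threshold, with ratios of 1.09 for 2L, 1.08 for 3L and 0.922 for 3R. With a global IDR of 0.001 or less 3R also passed, with a ratio of 0.899 (exact binomial test, adjusted p = 0.0412). Of the 88 passing peaks on the arms that were missing from the conservative list, 46 were on 3R. The ratios take no account of this removal.

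**Figure D4:**
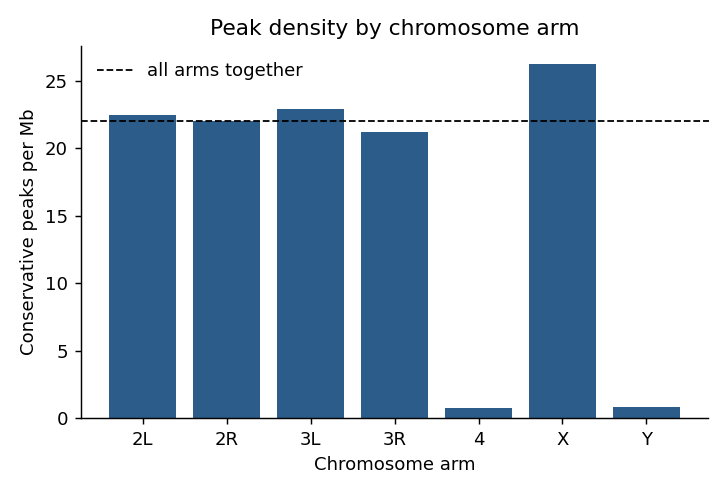
Conservative peaks per Mb (bars, y axis) on each chromosome arm (x axis), with the density over all arms as a dashed line. X had 26.2 peaks per Mb, chromosome 4 had 0.742 and Y had 0.818.

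The DNA at the summits was rich in A and T. Within 50 bp of the 3029 summits the GC content was 33.2%, and in windows 300 bp to either side it was 44.4%, a mean difference of -11.2 percentage points (SE 0.237). It was -15.8 points (SE 0.707) for the 300 strongest peaks and -7.72 (SE 0.435) for those ranked below 2000. Summits within 500 bp of a start and summits farther away had differences of -11.7 and -10.8 points. The values were -12.0 in replicate 1's own list and -11.4 in that of replicate 2. These composition values were computed after the data were examined.

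**Figure D5:**
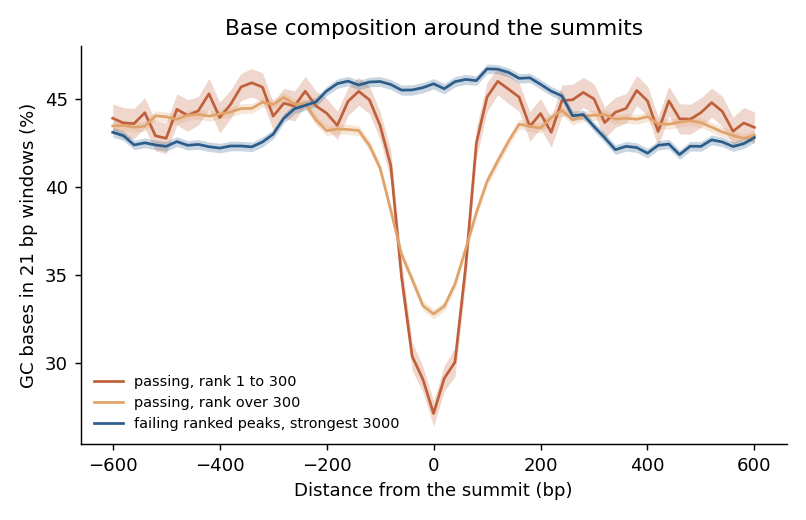
GC content in percent of 21 bp windows (y axis) by distance from the summit in bp (x axis); lines give means and bands the SE, for the 300 strongest conservative peaks, the weaker ones, and the 3000 strongest ranked peaks that failed the threshold. The passing groups drop at the summit, to under 30% in the strongest 300, and the failing group does not.

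Of the 20 motifs, 6 were more frequent at the summit than in the control window and 3 less frequent. The homeodomain core TAATTA occurred at 10.1% of summits against 5.08% of control windows (exact McNemar test, adjusted p = 9.11e-13). The CTCF core, the site of an insulator protein, occurred at 1.75% (53 summits) against 0.165% (5 windows), with an adjusted p of 5.5e-11. The DRE, a core promoter element bound by DREF, was found at 2.48% against 1.16%, the TATA box at 2.28% against 0.957%, the BEAF-32 element at 14.3% against 10.8%, and the twist-type E-box at 4.09% against 2.94% (exact McNemar tests, adjusted p = 0.000313, 0.000182, 0.00013 and 0.0386). The CA repeat occurred at 0.627% against 4.46% and the GAGA element at 0.528% against 3.24% (adjusted exact p = 1.92e-21 and 1.48e-14). The snail-type E-box was at 2.48% against 3.63% (adjusted exact p = 0.026). The BEAF-32 element did not pass with the control window to the right (adjusted exact p = 0.101). The twist-type E-box did not pass in the other thresholded list or in replicate 1's own list (adjusted exact p = 0.0854 and 0.0637), and neither E-box passed at a global IDR of 0.001 or less (adjusted exact p = 0.195 for both). Among peaks over 500 bp from a start, 4 motifs passed: the homeodomain core, the CTCF core, the GAGA element and the CA repeat.

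Since the summits differ from their flanks in base composition, each motif was also compared, after the data were examined, with patterns of the same letters in shuffled order. This test could not decide for short motifs, which have few letter orders, and the smallest p that 1000 shuffles can give is 0.002. Only 11 of the 20 motifs could have passed alone after adjustment, and for the homeodomain core, with 20 letter orders, the smallest p was 0.1. The lowest p was that of the CTCF core, whose log2 ratio of summit to control windows was 3.28 against a median of -1.59 for its shuffled patterns (permutation p = 0.004, adjusted p = 0.0799). For the homeodomain core the ratio was 0.99 against 1.44. The TATA box and the DRE have many letter orders (7560 and 5040). Their ratios were 1.24 against 1.25 (permutation p = 0.963) and 1.09 against 0.89 (permutation p = 0.611). Neither was set apart from shuffled patterns of its own letters.

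The 8-base words that set summits apart were runs of A and T and, in the opposite direction, CA repeats. The first was TATTTTAA, seen only in the summit window of 105 peaks and only in the control window of 20 on 2L, 2R and X, and of 85 and 18 peaks on 3L, 3R and 4 (exact McNemar test, adjusted p = 3.41e-11). TATATTAA had 53 against 6 on the second set of arms (adjusted exact p = 2.51e-10). CACACACA was less frequent at the summit, with 5 against 54 (adjusted exact p = 3.81e-11). All 10 words taken from the first set of arms held on the second, 8 of them without a G or C.

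Soft-masked sequence was more frequent at summits than at shifted positions. Repeats were not separated from low-complexity DNA, and the shifted positions were not matched for base composition. Soft-masked bases made up 23.9% of the sequence within 50 bp of the summits, against 20.4% in shifted sets (SD 0.679; permutation test, two-sided, p = 0.002, the smallest they can give). Windows free of soft-masked bases made up 27.2% of the 3029 summits and 44.05% of 30290 shifted positions, a difference that was not tested.

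The tagged gene itself carried no conservative peak. The nearest summit lay 3277 bp from a start of CG14667. Within 10000 bp on either side of the gene there were 2 peaks, where 0.454 were expected at the density of 3R. That expectation takes no account of the gathering of peaks at gene starts. Ranked candidates in the same interval numbered 29, where 22.1 were expected. A transgene can add copies of this locus, so peaks there can come from copy number, which was not tested. One of the 2 conservative peaks lay at 5371577 to 5371912 with a pooled signal of 167 (rank 892), intergenic and 50 bp from a start of Polr2F, an RNA polymerase II subunit gene. The other lay at 5369724 to 5370059 with 110.7 (rank 1603), in a 5' UTR of CG31542.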

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

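The tests that set unmasked summits against shifted positions, that used the composition of failing peaks, or that used a global IDR of 0.001 were chosen only after the data were seen.

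A signal lay outside the chromosome arms, in data that no comparison used. The conservative list held 54 peaks on scaffolds, all of them unlocalised pieces of X, with a median pooled signal of 107 and a maximum of 1040. Replicate 1's own list held 21 such peaks (0.778% of the list) and replicate 2's held 94 (4.38%).

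A further 143 ranked peaks met the authors' limit and were missing from the conservative list. Of these 88 were on the arms, 46 of them on 3R, and 55 on scaffolds. All 55 passing peaks on scaffolds other than the unlocalised X pieces were among those missing. The strongest of them, with a signal of 2215, lay on an unplaced scaffold at 6155 to 6439 and exceeded the maximum of 2115 in the conservative list. On the arms the strongest was in ush, on 2L at 480919 to 481254 with a signal of 1910, followed by peaks in Lk6 (1224) and larp (865.9), named here after their values were seen.

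The AT-rich sequence at the summits was weighed against technical explanations. A trend of signal over control with base composition was predicted to lower the GC content also at ranked summits that failed the threshold. There the summit was higher in GC than its flanks by 3.90 percentage points (SE 0.0306). These peaks were selected for failing, so a trend that lifted AT-rich candidates past the threshold could leave a GC-rich remainder. The comparison therefore could not decide, and this explanation stays open. Low-complexity sequence was tested on the 824 passing peaks with no soft-masked base within 50 bp, whose difference of -3.24 points (SE 0.44) fell between the bounds set in advance and decided nothing. Shifted positions with no masked base had 3.53 points, so passing peaks lay below them by a difference of -6.77 points (SE 0.449), which argues against masked sequence as the whole cause. A preference of the tagged protein for AT-rich DNA, or for open regions that are AT-rich, stays a hypothesis, and no biological explanation was tested.

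Few ranked peaks lay on chromosome 4. The ranked list held 33 there, 24.5 per Mb against 858 to 1032 per Mb on 2L, 2R, 3L, 3R and X, and the replicates' own ranked lists held 40 and 24. Base composition learned on 2L, 2R, 3L and 3R predicted 661 peaks, 20.04 times the number seen, and the density per unmasked Mb was 0.029 of the median of the other arms, so neither composition nor masked repeats accounts for the gap. The copy number of chromosome 4 in the control library could do so and was not tested, and no biological explanation was tested.

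The ribosomal protein genes among the bound genes stand apart in sequence. Summits at their starts did not show the drop in GC: the difference from the flanks was 4.14 points (SE 1.89, 35 summits) against -12.1 at other starts (SE 0.357, 1348 summits), a gap of 16.2 points (SE 1.92). The bound set in advance for nonspecific signal at highly transcribed genes was 10 points or more, so such a signal may account for these peaks, and a different promoter composition of these genes stays open. Peaks just past the threshold are not the reason, since with a global IDR of 0.001 or less the adjusted p was 1.25e-05 (Fisher's exact test). No biological explanation was tested.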

How the results depend on the processing

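The settings with a global IDR of 0.001, a pooled signal of 40 or more, the nearest gene only, two-sided tests, a non-coding background, shuffled letters or bases, and units limited by ranked peaks or coding starts were chosen after seeing the data. A limit of 0.01 on the global IDR removed no peak, since the deposited lists already met it. Replicate overlap, signal concordance, promoter location, divergent promoters and repeat content kept their direction and their side of the threshold, or their count within 1.5 times, under every setting run.

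The peak count was 1669 with a global IDR of 0.001 or less and lay between 2146 and 2699 in the replicates' own lists. The number of arms past the threshold was 3 to 6 with 1 replicate left out. The number of gene lists past the threshold was 5 without either replicate, 4 within 250 bp, 1 within 1000 bp, 1 with a global IDR of 0.001 or less, 1 with the nearest gene only, and 10 with two-sided tests, of which 6 had fewer bound members than the background. It was 7 with two-sided tests and non-coding genes alone as the background of the non-coding lists. All 10 first sequence words held under each setting except shuffled bases, where the 10 words were different ones, 7 held, and the first was less frequent at the summits. Cytoplasmic ribosomal proteins passed under all 11 one-sided settings (adjusted p up to 0.000151) and vesicle transport under 7 of them (adjusted p up to 0.676). These 11 include the main setting and the limit of 0.01 on the global IDR, which repeats it. The bound share of the transcription machinery list turned to below the background with the nearest gene only (8.60%). The motif count was 4 among peaks over 500 bp from a start and 0 against shuffled letters, a test that 9 of the 20 motifs could not pass alone. The CG14667 locus held 1 peak with a global IDR of 0.001 or less and 4 within 50000 bp on either side. The causes of these changes were not tested.

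Of 104 named genes, 101 were on the same side of the 500 bp limit in the other thresholded list, 87 in replicate 2's own list and 95 in replicate 1's. Depth could not be assessed from peak lists.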

Other observations

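The tests in this part were chosen after the data were examined. Tested two-sided, 6 lists had fewer bound members than the background. Chemoreceptor and odorant-binding protein genes had 2 of 228 bound (0.877%, Fisher's exact test, two-sided, adjusted p = 1.75e-09), Obp99b (113.5) and Obp83g (84.5), although 164 of the 228 had a ranked peak at a start. Cuticle protein genes had 0 of 117 (adjusted exact p = 2.13e-06), with a ranked peak at 95 of them. The tRNA genes had 4 of 295 bound (adjusted exact p = 1.06e-08), microRNA genes 4 of 260 (1.59e-07 after adjustment) and snoRNA genes 11 of 257 (0.0022 after adjustment). These 3 calls rest on a background that is mostly protein-coding. Against the 4219 non-coding genes alone, of which 144 were bound (3.41%), none of them passed (adjusted exact p = 0.141 for tRNA genes, 0.246 for microRNA genes and 0.630 for snoRNA genes), and the snoRNA share of 4.28% was above that background. Within 1000 bp 29 of the 257 snoRNA genes were bound (11.3%), against 12.9% of the background. Replicate 2's own list gave 2 bound tRNA genes and 1 bound microRNA gene, and that of replicate 1 gave 6 and 5. For chemoreceptors the counts were 2 and 1. Replication-dependent histone genes had 0 of 111 (adjusted exact p = 4.21e-06), but only 2 of the 111 had any ranked peak at a start, so candidates were almost absent there. Antimicrobial peptide genes had 0 of 32 (adjusted exact p = 0.0817), and dosage compensation genes 0 of 6.

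The remaining lists held few bound members and passed no test of more or fewer. They were muscle structure with 4 of 27, led by Msp300 (338.1) and sls (236.3) but 1 of 27 within 250 bp, ecdysone genes with 4 of 21, among them Eip75B (138.8), usp (107.8) and EcR (58.6), neuronal function with 2 of 34, Nrx-1 (206.5) and comt (85.7), germ plasm and piRNA genes with 2 of 23, cuff (125.2) and spn-E (66.8), and spliceosomal snRNA genes with 1 of 32, snRNA:U1:21D (62.5). The only bound member of the eggshell and yolk list, of 16, was Cp190, which is not an eggshell gene. Several of these counts rest on peaks missing from a replicate's own list. EcR, comt, spn-E and snRNA:U1:21D had a peak at a start in neither, and cuff and Eip75B had none in replicate 2. In replicate 2's own list 1 ecdysone gene, 1 gene of neuronal function, 0 germ plasm and piRNA genes and 0 spliceosomal snRNA genes were bound, and in that of replicate 1 the numbers were 3, 1, 1 and 2.

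When the summit windows were compared with shuffled copies of themselves that kept their dinucleotides, 7 of the 10 first words held on the second set of arms. The first of them, AAAAATTT, was less frequent at the summits than in the shuffled copies, with 44 peaks against 115 on the first set of arms and 43 against 74 on the second (exact McNemar test, adjusted p = 0.0076). The other words that held were more frequent at the summits. They included AAATATAT, with 95 against 35 and 112 against 34 (exact McNemar test, adjusted p = 6.42e-10), CACTGTGC, with 30 peaks against 2 on the first set and 15 against 0 on the second (exact McNemar test, adjusted p = 0.000305), CACAGTGG, with 31 against 2 and 15 against 1 (adjusted p = 0.00104), and GATGGCGC, with 21 against 1 and 12 against 0 (adjusted p = 0.00104). The last overlaps the CTCF core.

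Summits at ribosomal protein starts lay a median of 69.0 bp from the nearest start, against 137 bp at other starts.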
